A study of Mus musculus with 26 samples.

How the data were processed

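Polyadenylated RNA was sequenced from 10 mammary tumors of MMTV-PyMT mice and from 16 tumor organoid cultures, grown in Matrigel with FGF2. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from 1 µg with TruSeq chemistry; whether the kit kept strand is not given in the sources used here. Tumor mice received 125 mg/kg of oligonucleotide per week, and organoids 500 nM for 6 days, renewed on day 3, per the labels' protocols. Each library came with its own file of raw read counts per gene, as deposited by the authors. Per the submitters' processing notes, CASAVA, FastQC, STAR, HTSeq and DESeq2 were used with the mm9 genome build; versions, roles, options and the annotation are not given in the sources used here.

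Each table held 37310 genes and 5 further lines for reads not assigned to a gene. Those lines were left out of library sizes and tests. Relative to the reads assigned to genes, in tumors they held 11.1 to 24.5% for reads in no feature, 3.90 to 4.65% for ambiguous reads and 24.1 to 44.0% for reads with several alignments, and in organoids 8.34 to 14.6%, 4.44 to 8.70% and 21.2 to 32.7%. The lines for low alignment quality and for unaligned reads held 0 in every library. Reads assigned to genes ranged from 9939520 to 51363552 in tumors and from 23973533 to 65146030 in organoids. Because reads with several alignments were not counted for a gene, and because strand may not have been used, values of ribosomal protein genes, histones and other genes with near-identical copies, and of genes that overlap another on either strand, are uncertain.

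Gene IDs were matched to GENCODE M21 on GRCm38 for symbols, position, length and GC content. Of the 37310 IDs, 32620 matched a symbol and 4690 did not, and 6 matched IDs shared a symbol with another. The tables hold no coordinates, and the authors' build was another, so the position given for Malat1 is that of GRCm38. No read was counted for 8706 genes in any library.

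Groups and replicate numbers were taken from the sample titles. Tumors and organoids were fitted separately with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15) in R 4.3.3, with all groups of a system in the fit so that they shared 1 estimate of the spread. The difference between the tumor and the organoid response was a contrast in a fit of both systems. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, per comparison. Standard errors of log2 fold changes are the fold change divided by the square root of the quasi-likelihood F statistic. CPM values used TMM-scaled library sizes, and log2 CPM a prior count of 2. Principal components were computed on the 500 most variable genes.

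A set of 32 gene lists (pathways, cell types and the neighbours of Malat1) was fixed before the data were examined, with 752 members of which 744 matched. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with a correlation estimated per list, with ranks, and with fry, and adjusted over the lists of a comparison. Camera compares a list with the other genes; fry asks whether its genes move on balance in 1 direction, and compares it with nothing else. The genes named were those of a rule also fixed beforehand: Malat1 and Neat1, up to 10 called genes per direction for both ASOs, the 5 with the smallest p per direction for single comparisons (each with a mean log2 CPM of at least 1), and per list described up to 4 members with the smallest p and the most abundant member. The rule was also applied to the fits with the replicate block, a use chosen after values were seen. Some genes that the rule picks are not reported here. Differences of single values were tested with exact two-sided permutation tests over all splits of the libraries.

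Replicate numbers are shared between groups, and whether they pair the libraries was checked from deviations from the group means. In organoids, libraries with the same number correlated at 0.469 to 0.933 (median 0.817) and 24 of 24 pairs exceeded 0.1, while pairs with different numbers had a median of -0.32, and 99.4% of the variance of the first principal component lay between numbers. The numbers thus pair the organoid libraries, although the labels do not say what they share. In tumors 2 of 9 pairs exceeded 0.1, so that tumors share only a number. Libraries of the same group were compared for near-identical counts: chi-square values per degree of freedom lay between 15.0 and 447, and none were alike within sampling noise. The lowest, 15.0, was that of scASO organoid 1 and the library labelled scASO replicate 2. Samples far from others in groups of 4 were sought with Dixon's ratio (limit 0.829).

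The fit was tested on simulated counts with the means, spread and library sizes of the real data, in which 100 genes were changed 2-fold and 100 genes 4-fold. For both ASOs in tumors 26 and 76 were recovered (17048 genes), for ASO1 in tumors 17 and 73 (17036 genes), for both ASOs in organoids 40 and 82 (16894 genes), or 94 and 99 with the replicate block (16957 genes), and 98 and 99 with the block and without the 2 libraries that went against their labels (17143 genes). For scASO against Mock with the block 88 and 98 were recovered (16961 genes), and for the difference of the responses 14 and 71 (17839 genes). Among unchanged genes 5, 5, 4, 11, 6, 11 and 8 were called in the same order, and no recovered gene had the wrong sign.

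Alternatives fixed beforehand were DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, DESeq2 size factors in edgeR, no filter, the replicate block, only the compared groups in the fit, Mock in place of scASO as the control, the fit without Mock, other settings of camera, and leaving out each library in turn. Leaving out the library labelled ASO2 replicate 1 and the library labelled scASO replicate 2, the block with Mock as control, DESeq2 with the block and the block for the lists of scASO against Mock were added after seeing the data. The division of the scASO libraries by replicate number and the lists of each tumor comparison with 1 tumor left out were added then as well. Chance values for comparisons with shared controls came from simulated unchanged groups that shared simulated controls. All libraries, the controls included, were drawn from the means of the control group. Each gene was drawn on its own, without correlation between genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.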

Results

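Gene counts from 26 RNA sequencing libraries were compared. They came from mouse mammary tumors driven by the polyoma middle T antigen under the MMTV promoter, a mammary-active viral promoter, and from organoids grown from such tumors. Antisense oligonucleotides (ASOs), short modified DNA strands that lead RNase H to cut a complementary RNA, were directed against Malat1, a long noncoding RNA that collects in nuclear speckles next to splicing factors. The series title names tumor differentiation and metastasis after Malat1 loss as its subject. The comparisons ask which genes differed in tissue or culture given either of the Malat1 ASOs. Mice received 125 mg/kg of ASO per week. Of the 10 tumors sequenced, 3 had ASO1, 4 had ASO2 and 3 had the control oligonucleotide scASO. Organoids were kept with 500 nM oligonucleotide for 6 days, with 4 libraries for each of ASO1, ASO2, scASO and Mock (no oligonucleotide is named for Mock in the labels).

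Reads assigned to genes numbered 22.6, 51.4 and 29.5 M in the ASO1 tumors, 28.3, 31.2, 24.5 and 9.94 M in the ASO2 tumors, and 35.8, 33.8 and 22.4 M in the scASO tumors. The organoid libraries held 39.9, 40.0, 60.7 and 44.3 M with ASO1 and 40.0, 36.1, 40.3 and 65.1 M with ASO2. They held 38.4, 39.0, 23.97 and 25.7 M with scASO and 39.4, 36.4, 40.5 and 25.95 M with Mock, each in the order of the replicate numbers. The labels do not say whether the replicates were separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

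Malat1 (ENSMUSG00000092341) lies on chromosome 19 from 5795690 to 5802672 on the minus strand in the GRCm38 build, where it is annotated as a long intergenic noncoding RNA. In tumors it was at 765 ± 261 CPM (normalised read counts scaled to a common library total; SD, n = 3) with ASO1 and 722 ± 249 (n = 4) with ASO2, against 1640 ± 631 (n = 3) with scASO. The geometric mean over the 7 ASO tumors was 45.7% of that in scASO tumors (exact two-sided permutation test, p = 0.0167 over 120 splits). For ASO1 alone 47.2% remained, with an exact permutation p of 0.1, the smallest that 3 against 3 tumors allow. For ASO2 alone 44.5% remained (exact permutation p = 0.0857). In the model of all genes the log2 fold change over both ASOs was -1.14 ± 0.32 (SE). Its unadjusted p was 0.00501 and its adjusted p 0.827 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Knockdown was partial: the lowest scASO tumor, at 944.7 CPM, lay below the highest ASO tumor, at 1035 CPM.

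In organoids Malat1 was at 117 ± 37.6 CPM (n = 4) with ASO1, 479 ± 581 (n = 4) with ASO2, 682 ± 425 (n = 4) with scASO and 1017 ± 396 (n = 4) with Mock. A pair of libraries went against their labels. The library labelled ASO2 replicate 1 held 1343 CPM while the other ASO2 libraries held 198.1, 88.6 and 287 CPM. The library labelled scASO replicate 2 held 106 CPM while the other scASO libraries held 762, 730 and 1130 CPM. With both kept, 35.4% of Malat1 remained over the 8 ASO libraries relative to scASO (exact permutation p = 0.121). Relative to Mock 18.8% remained (exact permutation p = 0.0101). Without these 2 libraries, a choice made after their values were seen, 13.2% remained with ASO1 (exact permutation p = 0.0286). With ASO2 it was 20.03% (exact permutation p = 0.1, the smallest possible), and 15.8% over both (exact permutation p = 0.00833). Neat1, the neighbouring long noncoding RNA that builds paraspeckles, differed by a log2 ratio of 0.03 between ASO and scASO tumors (exact permutation p = 0.967) and of -0.07 between ASO and scASO organoids (exact permutation p = 0.766). By ASO, tumors held 70.1% of the scASO level of Neat1 with ASO1 (log2 ratio -0.51, exact permutation p = 0.4) and 135% with ASO2 (log2 ratio 0.43, exact permutation p = 0.514).

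**Figure D1:**
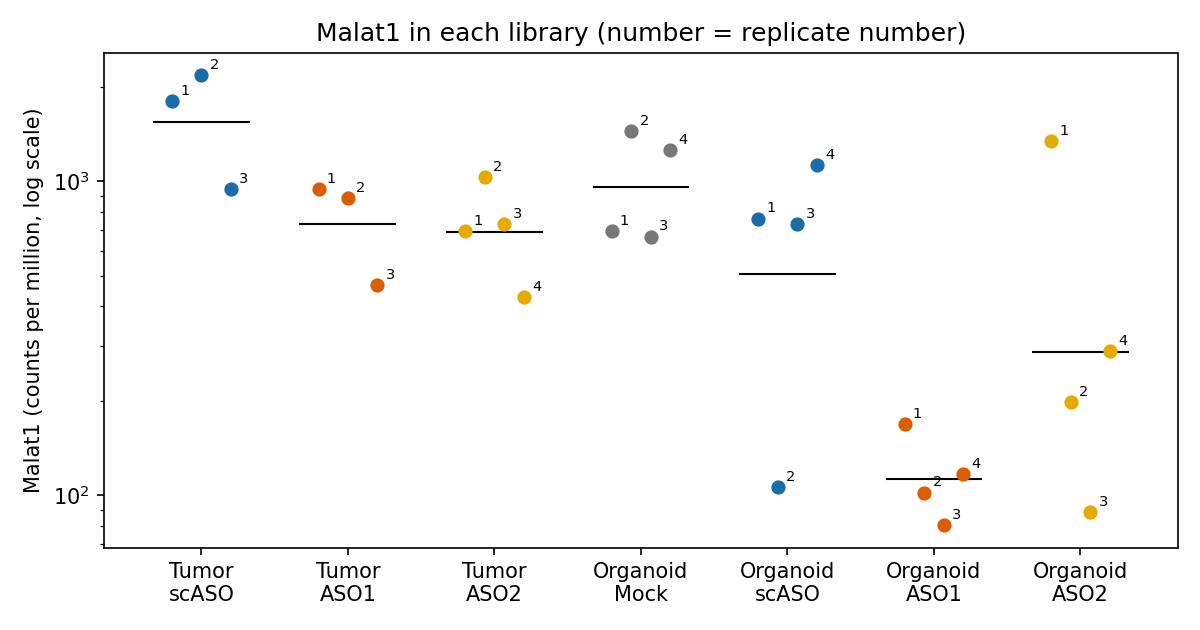
Malat1 in each of the 26 libraries, in CPM on a log scale, with the replicate number beside each point and a line at each group's geometric mean. The library labelled ASO2 replicate 1 (1343 CPM) and the library labelled scASO replicate 2 (106 CPM) lie apart from the other organoid libraries of their groups.

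Organoid libraries grouped first by replicate number. Deviations from the group means correlated across genes at 0.469 to 0.933 in all 24 pairs of libraries that share a number. The first principal component, with 82.4% of the variance of the 500 most variable genes, set number 4 (scores of 76.7 to 92.7) apart from number 3 (-21.2 to -17.3) and from numbers 1 and 2, which overlapped (-38.5 to -31.1 and -34.6 to -27.4). Of its variance 99.4% lay between numbers. Treatment took 67.7% of the fourth component, which held 0.888% of the variance. When each ASO2 and scASO library was set against number profiles built from ASO1 and Mock libraries with Malat1 left out, 6 of 8 correlated best with their own number. The library labelled ASO2 replicate 1 correlated at 0.529 with number 1 and at 0.796 with number 2. The library labelled scASO replicate 2 correlated at 0.556 with number 2 and at 0.747 with number 1. Organoid values below are therefore also given with the replicate number as a block where it changes a call, and without these libraries.

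**Figure D2:**
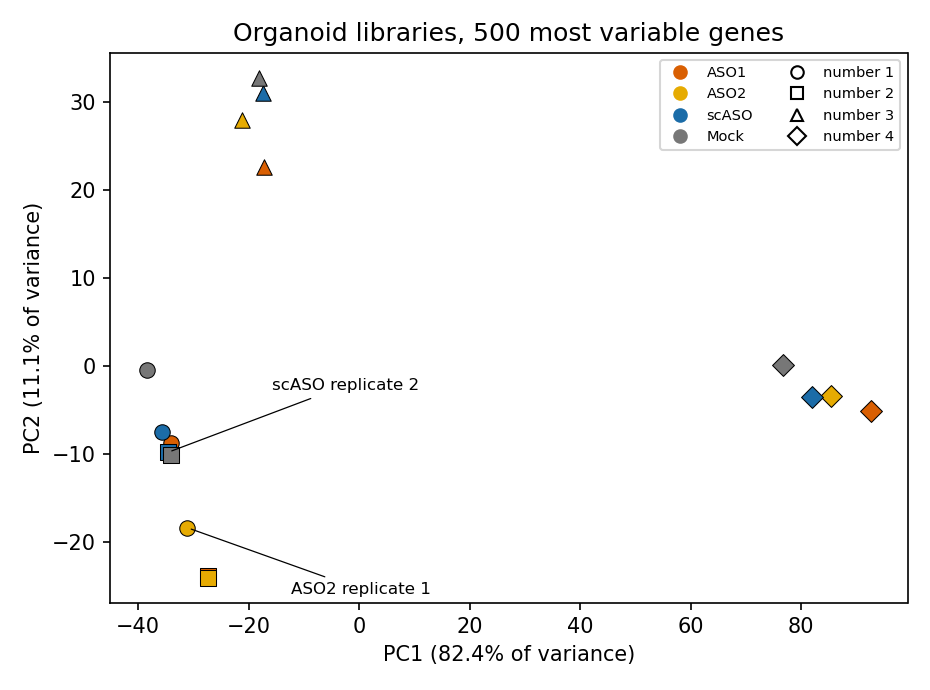
The first and second principal components of the 16 organoid libraries over the 500 most variable genes (log2 CPM), with treatment as color and replicate number as symbol. Numbers 3 and 4 lie apart from each other and from numbers 1 and 2, which lie close together. The library labelled ASO2 replicate 1 and the library labelled scASO replicate 2 are marked.

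In the tumors, proliferation genes were higher after Malat1 ASOs. All 28 measured genes of the G2/M cell cycle list had higher estimates over both ASOs, with a median log2 fold change of 0.72. Among them were Ndc80 of the kinetochore (0.95 ± 0.30, SE), the spindle checkpoint kinase Bub1 (0.99 ± 0.33), the mitotic kinase Cdk1 (0.81 ± 0.27) and the proliferation marker Mki67 (0.63 ± 0.27). For the G1/S cell cycle list, 24 of 25 were higher with a median of 0.54. These included Rpa2, which binds single-stranded DNA (0.55 ± 0.21), Tyms, which makes thymidylate (0.54 ± 0.20), cyclin Ccne2 (0.75 ± 0.31) and Rrm1, a subunit of ribonucleotide reductase (0.52 ± 0.30). By camera with a preset correlation between genes of 0.01 the lists' adjusted p were 1.49e-18 and 3.03e-09. With an estimated correlation they were 0.405 and 0.508, and 0 members of either list passed on their own, adjusted over the list alone or over all genes. Without ASO1 tumor 2 the G1/S median was 0.33 (adjusted p = 1.04e-05).

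Genes of other tissues also differed between these tumors. Of 19 adipocyte genes, 18 were higher with a median of 2.58. They included the fatty acid transporter Cd36 (2.53 ± 0.63), the lipid droplet protein Plin1 (7.50 ± 1.86) and the fatty acid carrier Fabp4 (3.24 ± 0.98), while the most abundant member, the lipase Pnpla2, was at -0.16 ± 0.16. By camera the adjusted p was 1.08e-11, and adjusted p = 0.405 with an estimated correlation. Adjusted over the list alone 11 adipocyte genes were called, and 0 over all genes. The 11 became 0 without ASO1 tumor 3, ASO2 tumor 3 or any of the 3 scASO tumors, 1 without ASO2 tumor 1 or ASO2 tumor 4, and 7 without ASO1 tumor 1. All 22 skeletal muscle genes had higher estimates over both ASOs with a median of 1.59, such as the myosin Myh2 (3.13 ± 1.52) and the actin Acta1 (1.90 ± 1.71). The list had adjusted p = 0.00569, and adjusted p = 0.679 with an estimated correlation. Over both ASOs the muscle list rested on ASO2 tumor 1, without which its median was -0.18 and its adjusted p 0.939. Without the same tumor the adipocyte median stayed at 2.22 (adjusted p = 4.79e-08). The muscle list was also not called without scASO tumor 1 (adjusted p = 0.0587) or scASO tumor 2 (adjusted p = 0.0625), and without scASO tumor 3 its median was 2.99. With ASO1 alone, muscle genes went the other way, with 16 of 22 lower and a median of -0.80, and the list was not called (adjusted p = 0.122). It was called lower with ASO1 without ASO2 tumor 1 (adjusted p = 0.0428), scASO tumor 1 (0.0236) or scASO tumor 2 (0.0137), and its median was -0.051 without scASO tumor 3. All 24 genes of the fibroblast and pericyte list were higher (median 0.55), such as the matrix genes Fbln1 (1.73 ± 0.49) and Postn (0.57 ± 0.51). This list had adjusted p = 6.23e-05, and adjusted p = 0.567 with an estimated correlation. Its median was 0.36 without ASO1 tumor 3 and 0.84 without scASO tumor 3.

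Lists of epithelial genes went in different directions in the same tumors. In the list epithelial junctions and adhesion, 24 of 28 genes were lower after Malat1 ASOs with a median of -0.22. Lower members were Tjp3 of tight junctions (-0.45 ± 0.14), plakoglobin Jup (-0.40 ± 0.16), the desmosomal cadherin Dsg2 (-0.40 ± 0.17) and E-cadherin Cdh1 (-0.38 ± 0.16), while beta-catenin Ctnnb1, the most abundant member, was at 0.48 ± 0.38. The adjusted p was 3.15e-06, and adjusted p = 0.405 with an estimated correlation. For squamous keratins and cornification, 11 of 13 measured genes were lower with a median of -0.45. They included keratin Krt16 (-3.96 ± 1.12), the cadherin Dsg3 (-2.27 ± 0.73) and Sbsn (-0.30 ± 0.37). Here adjusted p = 0.00145, and adjusted p = 0.508 with an estimated correlation. Without scASO tumor 1, Krt16 was at 0.11, Dsg3 at -0.21 and the squamous list at adjusted p = 0.968 with a median of 0.11. Its median was -1.25 without ASO1 tumor 3, -0.89 without scASO tumor 3, -0.79 without ASO1 tumor 1 and -0.78 without scASO tumor 2, where 0, 4, 0 and 3 members were called adjusted over the list alone. Of the basal and myoepithelial list 16 of 20 genes were higher (median 0.31, adjusted p = 0.0397, and adjusted p = 0.679 with an estimated correlation). This list was not called without ASO1 tumor 1 (adjusted p = 0.124), ASO1 tumor 3 (0.495), ASO2 tumor 2 (0.14), ASO2 tumor 3 (0.0924) or scASO tumor 3 (0.917). Its median was 0.75 without scASO tumor 2 (adjusted p = 4.9e-05), 0.20 without ASO2 tumor 2 and 0.099 without scASO tumor 3. The luminal epithelium list was not called (10 of 22 higher, adjusted p = 0.316), but was called lower without ASO1 tumor 3 (adjusted p = 0.0126) or scASO tumor 2 (0.0207). The type I interferon response list was higher in 29 of 30 genes (median 0.48), with Ifi27l2a at 1.63 ± 0.86 and the transcription factor Irf7 at 0.32 ± 0.46. Its adjusted p was 0.0012, and adjusted p = 0.679 with an estimated correlation. For cytoplasmic ribosomal proteins 32 of 33 were higher (median 0.34), with Rpl38 at 0.67 ± 0.23 and Rpl4 at 0.41 ± 0.24. Camera gave adjusted p = 2.16e-08, and adjusted p = 0.405 with an estimated correlation. For the mesenchymal transition list 20 of 24 genes were higher (median 0.55, adjusted p = 0.02, and adjusted p = 0.529 with an estimated correlation). The interferon list was not called without ASO1 tumor 2 (median 0.043, adjusted p = 0.987) or scASO tumor 2 (adjusted p = 0.151). The mesenchymal transition list was not called without ASO1 tumor 3 (0.297), ASO2 tumor 2 (0.0513), scASO tumor 2 (0.0769) or scASO tumor 3 (0.115). Without ASO1 tumor 3 its median was 0.24. Macrophage genes were higher in 18 of 22 (median 0.34, adjusted p = 0.0348, and adjusted p = 0.679 with an estimated correlation). They were not called without ASO1 tumor 3 (adjusted p = 0.993), ASO2 tumor 1 (0.112), ASO2 tumor 3 (0.0531), scASO tumor 1 (0.0542) or scASO tumor 3 (0.459), and their median was 0.52 without ASO1 tumor 2 (adjusted p = 5.42e-07). The MMTV-PyMT malignancy and invasion list was lower in 16 of 28 genes (median -0.12, camera adjusted p = 0.0242). Without ASO1 tumor 2 it was not called (adjusted p = 0.1135). In all, camera with the preset correlation called 17 of the 32 lists, 13 higher and 4 lower, and 0 with an estimated correlation.

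Gene by gene, few differences stood above the spread between tumors. For both ASOs against scASO, edgeR's quasi-likelihood test called 0 of 17354 genes (1017 at an unadjusted p under 0.05). Limma voom with quality weights called 0, and DESeq2 called 18, of which 5 were higher and 13 lower. In simulated tumors of the same depth and spread, 26 of 100 genes changed 2-fold and 76 of 100 changed 4-fold were recovered. Changes of 2-fold were thus mostly below the reach of these libraries.

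With ASO1 alone, 1 of 17354 genes passed in tumors (edgeR, 1466 at an unadjusted p under 0.05). Slc47a1, an exporter of organic cations, rose from 1.77 ± 0.585 CPM (n = 3) with scASO to 29.8 ± 17.7 CPM (n = 3). This is a log2 fold change of 4.07 ± 0.45 (SE) with an adjusted p of 0.0442 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With ASO2 it was at 4.91 ± 0.639 CPM (n = 4), a log2 fold change of 1.47 ± 0.40. The G2/M cell cycle list was higher in 28 of 28 genes (median 0.95, the kinetochore protein Cenpf 0.90 ± 0.24, Bub1 1.35 ± 0.38, Mki67 0.91 ± 0.31). Of these 19 were called adjusted over the list alone and 0 over all genes. The list had adjusted p = 9.28e-20, and adjusted p = 0.31 with an estimated correlation. Without ASO1 tumor 2 its median was 0.53 (adjusted p = 9.7e-09). The 19 became 0 without ASO1 tumor 2 or any of the 3 scASO tumors. In the endothelium list 21 of 22 genes were higher (median 0.76), such as the capillary lipase anchor Gpihbp1 (1.52 ± 0.41), VE-cadherin Cdh5 (0.88 ± 0.29), claudin Cldn5 (1.16 ± 0.39) and Pecam1 (0.97 ± 0.42). By camera the adjusted p was 4.71e-07, and adjusted p = 0.478 with an estimated correlation. Without ASO1 tumor 3 the endothelium median was 0.37 (adjusted p = 0.00653). In the list milk protein and secretory differentiation, 18 of 26 genes were lower (median -0.57). Among them were the lactose synthase subunit Lalba (-3.22 ± 0.53, the only member called adjusted over the list alone), the mucin Muc1 (-1.09 ± 0.33) and the casein Csn3 (-0.99 ± 0.53). The adjusted p was 7.29e-06, and adjusted p = 0.31 with an estimated correlation. Slc47a1 was no longer called without ASO1 tumor 2 or without any of the 3 scASO tumors, where the count was 0. DESeq2 called 130 genes (60 higher, 70 lower), and with dispersions from the compared groups alone edgeR called 0.

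With ASO2 alone, edgeR called 0 of 17354 genes in tumors (892 at an unadjusted p under 0.05, and 1 called without ASO2 tumor 2). Limma voom called 0 and DESeq2 44, of which 39 were higher. All 19 adipocyte genes were higher (median 3.87, Cd36 3.87 ± 0.70, Plin1 9.92 ± 1.84), of which 13 were called adjusted over the list alone and 0 over all genes. For this adipocyte list adjusted p = 1.43e-25, and adjusted p = 0.353 with an estimated correlation. All 22 skeletal muscle genes were higher (median 4.48, Mylpf 5.23 ± 1.75, Acta1 4.87 ± 2.05), 20 of them called adjusted over the list alone and 0 over all genes. The muscle list had adjusted p = 9.92e-09, and adjusted p = 0.527 with an estimated correlation. Without ASO2 tumor 1 the muscle median was 0.85, with Mylpf at 1.66 and Acta1 at 0.99, 20 of 21 measured genes higher and 0 called adjusted over the list alone (adjusted p = 0.0032). That count of 20 was also 0 without ASO1 tumor 1, which enters the shared spread, or without any of the 3 scASO tumors. As mean log2 CPM, skeletal muscle genes were at 6.86, 1.72, -0.45 and 2.27 in ASO2 tumors 1 to 4. They were at -0.05, -0.22 and 1.69 in scASO tumors 1 to 3. In the list milk protein and secretory differentiation 17 of 26 genes were higher (median 0.29), with Csn2 at 7.49 ± 1.74, Csn1s2a at 6.61 ± 1.49 and Csn3 at -0.40 ± 0.49. Here adjusted p = 0.0331, and adjusted p = 0.558 with an estimated correlation. This call ended without ASO1 tumor 2 (adjusted p = 0.0524), ASO2 tumor 2 (0.103), ASO2 tumor 3 (0.253) or scASO tumor 2 (0.25), and the median was 0.087 without ASO2 tumor 4 and 0.44 without scASO tumor 1. Set directly against each other, ASO1 and ASO2 tumors differed in this milk list, lower with ASO1 in 24 of 26 genes (median -0.88). Camera gave adjusted p = 6.08e-10, and adjusted p = 0.269 with an estimated correlation. The median was -0.55 without ASO1 tumor 2 and -0.54 without ASO2 tumor 4. In the endothelium list 21 of 22 genes were higher with ASO1 (median 1.05), and 14 were called adjusted over the list alone. This list had adjusted p = 3.19e-13, and adjusted p = 0.295 with an estimated correlation. Without ASO1 tumor 3 the 14 became 2, and without ASO2 tumor 4 they became 9. Against scASO, 17 of 22 endothelium genes were lower with ASO2 (median -0.23, adjusted p = 0.0104, and adjusted p = 0.558 with an estimated correlation). That call ended without ASO2 tumor 2 (adjusted p = 0.0806) or ASO2 tumor 4 (0.311), and the median was -0.39 without ASO2 tumor 3. Of the adipocyte genes 16 of 19 were lower with ASO1 (adjusted p = 2.83e-14, and adjusted p = 0.295 with an estimated correlation). No single gene separated the ASOs by edgeR (0 called, 1743 at an unadjusted p under 0.05, and 1 without ASO2 tumor 4) or limma voom (0). DESeq2 called 164, of which 72 were higher with ASO1.

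No gene was called by both ASOs in tumors with edgeR, and 1 was with DESeq2. The log2 fold changes of ASO1 and of ASO2 against the shared scASO tumors correlated at 0.327 across 17354 genes, with a covariance of 0.137. Unchanged groups that shared controls, all simulated, gave a correlation of 0.534 and a covariance of 0.128, with 0 genes called in common. The number for independent lists of these sizes is 0. With 3 scASO tumors the controls could not be divided, so part of any excess may come from the shared controls. Genes are not independent replicates.

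In organoids as labelled, cell cycle genes were lower with Malat1 ASOs than with scASO, the reverse of the tumors. All 28 genes of the G2/M cell cycle list were lower (median -0.40, Tpx2 -0.46 ± 0.23, Ccna2 -0.60 ± 0.31, Mki67 -0.55 ± 0.32), and 24 of 25 of the G1/S cell cycle list (median -0.36). Their adjusted p were 1.82e-19 and 6.51e-12, and adjusted p = 0.526 and 0.526 with an estimated correlation. This direction includes the library labelled ASO2 replicate 1 and the library labelled scASO replicate 2. Without them and with the replicate block, the G2/M median was -0.05 and the G1/S median 0.04, and neither list was called. In the list of macrophage genes, 18 of 22 were lower (median -0.64), with complement C1qa at -1.13 ± 0.55 and the lipopolysaccharide receptor Cd14 at 0.05 ± 0.48. The adjusted p was 1.05e-06, and adjusted p = 0.537 with an estimated correlation. Genes of hypoxia and glycolysis were higher in 28 of 28 (median 0.31, Gpi1 0.50 ± 0.26, pyruvate kinase Pkm 0.25 ± 0.14). By camera the adjusted p was 2.5e-08, and adjusted p = 0.526 with an estimated correlation. For cytoplasmic ribosomal proteins 28 of 33 were higher (median 0.31, Rpl37 0.60 ± 0.25, Rps15 0.46 ± 0.23, Rpl4 0.24 ± 0.21). They had adjusted p = 2.02e-07, and adjusted p = 0.526 with an estimated correlation. In total 7 of 32 lists were called, 4 higher and 3 lower, and 0 with an estimated correlation. The unfolded protein and integrated stress response list (20 of 26 higher) and cholesterol synthesis (21 of 23 higher) were the others. Their adjusted p were 0.00493 and 0.0316, and adjusted p = 0.63 and 0.78 with an estimated correlation. The stress response list was not called without ASO1 replicate 3 (adjusted p = 0.114), ASO2 replicate 3 (0.166), scASO replicate 1 (0.191) or the library labelled scASO replicate 2 (0.0728). For cholesterol synthesis this held without ASO1 replicate 3 (adjusted p = 0.114), ASO1 replicate 4 (0.187), ASO2 replicate 3 (0.166), ASO2 replicate 4 (0.229) or scASO replicate 1 (0.5). The replicate block added squamous keratins and cornification (18 of 22 higher, adjusted p = 5.04e-05, and adjusted p = 0.361 with an estimated correlation). It also added nerve and Schwann cell genes (9 of 11 lower, adjusted p = 0.00945, and adjusted p = 0.403 with an estimated correlation). Without the block this list was called in 11 of 12 fits with 1 library left out (camera adjusted p from 0.00184 to 0.191).

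Of 17126 genes tested in organoids, edgeR called 0 for ASO1 against scASO (44 at an unadjusted p under 0.05), 0 for ASO2 (287) and 0 for both (182), and DESeq2 called 0 in each. limma voom with quality weights called 0 for ASO1, 3974 for ASO2 and 1029 for both. ASO1 and ASO2 organoids differed in 0 genes by edgeR (26 at an unadjusted p under 0.05), DESeq2 and limma voom. In simulated libraries of this design 40 of 100 genes changed 2-fold and 82 of 100 changed 4-fold were recovered.

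Without the library labelled ASO2 replicate 1 and the library labelled scASO replicate 2, and with the replicate number as a block, edgeR called 4 of 17325 genes for both ASOs against scASO, all lower (1585 at an unadjusted p under 0.05). Simulated libraries of this fit recovered 98 of 100 genes changed 2-fold. Malat1 fell by 2.67 ± 0.23 on the log2 scale (SE, adjusted p = 0.000649 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 2 libraries were left out for their Malat1 levels, so this value is no independent test of the knockdown. Ptprc, the leukocyte surface marker CD45, was at -1.41 ± 0.19 (adjusted p = 0.0291). The sarcomere genes titin (Ttn) and perinatal myosin Myh8 were at -1.93 ± 0.26 and -4.78 ± 0.66 (each adjusted p = 0.0291). In the same fit scASO lay above Mock by 1.98 ± 0.30 for Ttn (adjusted p = 0.00843) and by 4.54 ± 0.71 for Myh8 (adjusted p = 0.00993). With ASO1 alone Malat1 was the 1 gene called, and with ASO2 alone Malat1, Ptprc and the autophagy protease Atg4c were the 3 called. Ptprc, Ttn and Myh8 lay below the abundance set for named genes and are named because the count was small. In the macrophage list 20 of 22 genes were lower (median -0.61, C1qa -0.95 ± 0.15, C1qb -0.73 ± 0.17, with Cd14 at -0.06 ± 0.09), 14 of them called adjusted over the list alone and 0 over all genes. Camera gave adjusted p = 1.75e-16, and adjusted p = 0.0731 with an estimated correlation. In the skeletal muscle list 18 of 19 were lower (median -0.65, Myh1 -2.03 ± 0.39), 10 of them called adjusted over the list alone and 1 over all genes. Its adjusted p was 5.34e-14, and adjusted p = 0.0731 with an estimated correlation. Genes of cholesterol synthesis were higher in 23 of 23 by a small amount (median 0.13, Mvd 0.31 ± 0.07, Fdps 0.27 ± 0.08), and splicing and nuclear speckle factors lower in 24 of 31 (median -0.10, Luc7l3 -0.23 ± 0.08, Srsf11 -0.17 ± 0.06). These lists had adjusted p = 5.52e-08 and 0.000549, and each adjusted p = 0.0731 with an estimated correlation. The type I interferon response list was lower in 27 of 30 genes (median -0.34, 2 called adjusted over the list alone and 0 over all genes). Its adjusted p was 1.49e-12, and adjusted p = 0.479 with an estimated correlation. As labelled and without the block it was higher in 19 of 30 (adjusted p = 0.503). In the self-contained test fry, which asks whether a list moves on balance in one direction, the cholesterol synthesis and splicing lists had adjusted p of 0.0135 and 0.00399. Camera with the preset correlation called 11 of 32 lists.

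The log2 fold changes of ASO1 and ASO2 against scASO organoids correlated at 0.787 as labelled (covariance 0.0905). Unchanged groups that shared controls, all simulated, gave 0.512 (covariance 0.179). With the replicate numbers included in the simulated counts they gave 0.520 (covariance 0.0353). With each ASO set against scASO in its own pair of replicate numbers, so that no library was shared, the correlation was 0.0521, 0.437, 0.212, 0.795, 0.791 and 0.232 in the 6 divisions. The divisions with 0.795 and 0.791 were those in which ASO1 of number 2 met the library labelled scASO replicate 2, and the library labelled ASO2 replicate 1 met scASO of number 1. With only the scASO libraries divided, so that numbers were not matched, all 6 correlations were below 0 (-0.274 to -0.0625). In the blocked fit without the 2 libraries the correlation was 0.726 (covariance 0.0637), against a simulated 0.601 (covariance 0.0357). Without these libraries the numbers could not be divided with 2 pairs on each side, so part of any excess may come from the shared controls. Malat1 was there the 1 gene called by both, against 0.000173 for independent lists of these sizes and a simulated mean of 0.05. The 2 libraries were left out for their Malat1 levels, which favors this call, so neither number tests it.

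The control oligonucleotide itself was compared with Mock. With the replicate block in the model, 94 genes were higher with scASO and 34 lower. The bone morphogenetic protein antagonist Grem1 rose by 1.93 ± 0.21 on the log2 scale (SE), the anion channel subunit Lrrc8c by 0.90 ± 0.09, the kinesin Kif1a by 0.95 ± 0.12, the matrix protease Adamts4 by 0.89 ± 0.11 and the actin crosslinker Flnc by 1.15 ± 0.14. Their adjusted p were 0.00316, 0.00274, 0.00653, 0.00653 and 0.00653 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the mesenchymal transition list 23 of 24 genes were higher (median 0.43), 4 were called over all genes and 13 adjusted over the list alone. Vimentin (Vim) rose by 0.92 ± 0.14, S100a4 by 1.38 ± 0.21, fibronectin (Fn1), the most abundant member, by 1.01 ± 0.19 and the transcription factor Zeb2 by 1.01 ± 0.21. The list was at adjusted p = 2.3e-13 by camera, adjusted p = 0.0425 with an estimated correlation, and adjusted p = 0.0037 by fry. In CPM, Fn1 was at 1400 ± 567 with scASO and 764 ± 478 with Mock (n = 4 each), and Vim at 296 ± 83.1 and 162 ± 61.2. In the fibroblast and pericyte list 18 of 22 genes were higher (median 0.45, the pericyte proteoglycan Cspg4 1.01 ± 0.20, with Postn at -0.09 ± 0.17). Called were 7 higher and 1 lower adjusted over the list alone and 1 over all genes. By camera the adjusted p was 2.63e-06, and adjusted p = 0.354 with an estimated correlation. Among the genes that fell were Fam234b (-0.58 ± 0.08), the nuclear envelope protein Syne4 (-0.63 ± 0.10), the proton pump subunit Atp6v1c2 (-0.60 ± 0.10), Rpl37 (-0.78 ± 0.13) and Cmas, which activates sialic acid (-0.41 ± 0.07). The cytoplasmic ribosomal proteins were lower in 30 of 33 (median -0.33, Rpl4 -0.33 ± 0.14, adjusted p = 8.96e-14, and adjusted p = 0.354 with an estimated correlation).

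With the block edgeR called 128 of 17126 genes for scASO against Mock (2699 at an unadjusted p under 0.05), and DESeq2 with the block called 588. Without the block, the design fixed beforehand, edgeR called 0 (272 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0. There 13 lists passed camera, 8 higher and 5 lower, the mesenchymal transition list at adjusted p = 3.37e-09, and adjusted p = 0.428 with an estimated correlation. The count of 128 fell to 1 without number 2, 22 without number 1, 10 without number 3 and 4 without number 4. With single libraries left out it ran from 5 without scASO 1 to 108 without Mock 1, with 54 without the library labelled scASO replicate 2. It was 10 without scASO 4, 14 without Mock 2, 19 without Mock 4, 45 without scASO 3 and 47 without Mock 3. The mesenchymal transition median stayed between 0.40 and 0.70 in these fits, with adjusted p of at most 8.81e-08 with the preset correlation. Without the library labelled scASO replicate 2 and the library labelled ASO2 replicate 1, the blocked fit called 308 of 17325 genes, 243 higher and 65 lower, of which 117 were among the 128. The mesenchymal transition median was 0.77, with 17 of 24 genes called adjusted over the list alone and 10 over all genes (adjusted p = 6.73e-23, and adjusted p = 0.00932 with an estimated correlation). In the skeletal muscle list 17 of 19 genes were then higher (median 1.23, Myh1 2.84 ± 0.46, with myoglobin Mb at -0.71 ± 0.18), 14 higher and 1 lower adjusted over the list alone and 6 over all genes. This list had adjusted p = 2.64e-13, and adjusted p = 0.126 with an estimated correlation.

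Other lists depended on the block in this comparison. Basal and myoepithelial genes (16 of 20 higher, adjusted p = 0.00489, and adjusted p = 0.354 with an estimated correlation) and macrophage genes (17 of 22 higher, adjusted p = 0.0122, and adjusted p = 0.584 with an estimated correlation) were called with it and not without it, in the fits of all libraries. The list milk protein and secretory differentiation was called without it and not with it (17 of 24 lower, adjusted p = 0.0459, and adjusted p = 0.553 with an estimated correlation). Without the 2 libraries that went against their labels and with the block, basal and myoepithelial genes (adjusted p = 0.00628) and milk genes (20 of 25 lower, adjusted p = 0.0112) were both called. Each had adjusted p = 0.43 with an estimated correlation, and macrophage genes were not called (adjusted p = 0.147). The milk list without the block was not called without scASO replicate 4 (adjusted p = 0.959), Mock replicate 1 (0.576), Mock replicate 2 (0.284) or Mock replicate 3 (0.635). The type I interferon response list was lower in 28 of 30 genes without the block (median -0.41, adjusted p = 6.03e-05, and adjusted p = 0.573 with an estimated correlation). With it 27 of 30 were lower (adjusted p = 0.000198, and adjusted p = 0.609 with an estimated correlation). The unblocked call ended without scASO replicate 4 (adjusted p = 0.0817), Mock replicate 2 (0.506) or Mock replicate 3 (0.0715), and the blocked call without the 2 libraries (adjusted p = 0.345). The MMTV-PyMT malignancy and invasion list, a set of known oncogenic and invasion genes of this tumor model, was higher in 19 of 28 genes with the block (median 0.10, 5 adjusted over the list alone and 0 over all genes). Its adjusted p was 0.00515, and adjusted p = 0.0988 with an estimated correlation. Without the block 20 of 28 were higher (adjusted p = 0.0371, and adjusted p = 0.428 with an estimated correlation). That call ended without scASO replicate 4 (adjusted p = 0.376), Mock replicate 1 (0.173) or Mock replicate 3 (0.333).

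**Figure D3:**
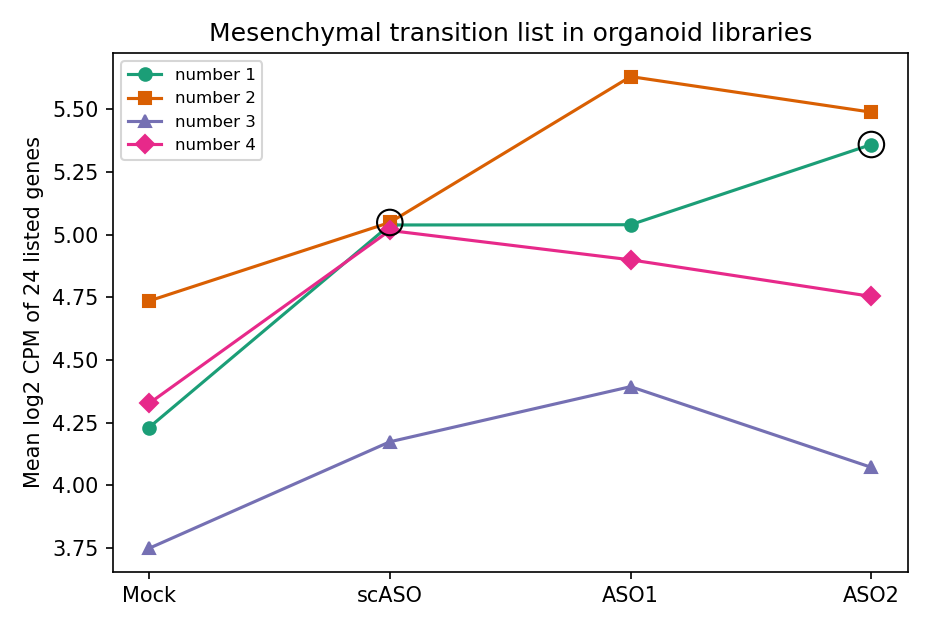
Mean log2 CPM of the 24 genes of the mesenchymal transition list in each organoid library (vertical axis), with lines joining libraries that share a replicate number. Circles mark the library labelled scASO replicate 2 and the library labelled ASO2 replicate 1. Each scASO library lay above the Mock library of its number.

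The Malat1 ASOs shared these differences from Mock. In the blocked fit of all libraries, ASO1 against Mock gave 407 called genes and ASO2 312. Both together gave 738, of which 527 were higher and 211 lower. The count of 738 became 424, 148, 193 and 235 without numbers 1 to 4. It was 414, 257, 447 and 396 without Mock 1 to 4, and 1709 without the 2 libraries that went against their labels. Without the block 0 were called for both (468 at an unadjusted p under 0.05). Lrrc8c rose by 0.87 ± 0.08, Flnc by 1.28 ± 0.13, Adamts4 by 0.98 ± 0.10, the trophoblast glycoprotein Tpbg by 0.57 ± 0.06 and the endocytic receptor Lrp1 by 0.96 ± 0.10 over both ASOs. Stxbp6 (-0.64 ± 0.08), Fam234b (-0.55 ± 0.07), the glutathione transferase Gsta3 (-0.76 ± 0.11), Dbt (-0.43 ± 0.06) and Limch1 (-0.73 ± 0.10) fell. In the mesenchymal transition list 22 of 24 genes were higher (median 0.68, Vim 0.85 ± 0.12, Fn1 1.07 ± 0.17, Cd44 0.58 ± 0.09, tenascin Tnc 1.57 ± 0.29), 9 of them called over all genes and 18 adjusted over the list alone, with 1 lower. Camera gave adjusted p = 4.61e-14, and adjusted p = 0.0318 with an estimated correlation. For squamous keratins and cornification 17 of 22 were higher (median 0.37, Klk8 1.08 ± 0.15, Dsg3 1.02 ± 0.15, Krt6a 1.06 ± 0.17, Krt16 0.97 ± 0.29), 4 called over all genes and 7 adjusted over the list alone. They had adjusted p = 1.47e-07, and adjusted p = 0.125 with an estimated correlation. Genes of cholesterol synthesis were higher in 22 of 23 (median 0.17, Mvd 0.31 ± 0.06, Srebf2 0.17 ± 0.08), 7 called over all genes and 10 adjusted over the list alone. Their adjusted p was 2.37e-07, and adjusted p = 0.0542 with an estimated correlation.

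Without the library labelled scASO replicate 2 and the library labelled ASO2 replicate 1, 253 genes were called with the same sign for scASO and for ASO1 against Mock, from 308 and 1159. Independent lists would share 12.2 (10.7 higher and 1.49 lower), and simulated unchanged groups shared 0.05 on average. For scASO and ASO2 against Mock 193 were shared, from 308 and 593, with 6.26 for independent lists (5.51 higher and 0.750 lower) and 0 in simulation. The simulated groups were unchanged and their genes varied independently, so shared counts near 0 were nearly fixed in advance. Neither number allows for shifts of whole Mock libraries, which both comparisons share. The shared counts therefore cannot be tested against them. Fold changes correlated at 0.724 (covariance 0.108) and 0.658 (covariance 0.0889). Simulated correlations were 0.449 and 0.389, with covariances of 0.0217 and 0.0209. With the Mock libraries divided so that scASO and the ASOs had different ones, the correlation was 0.515, 0.451 and 0.323 in the 3 divisions. There 20, 21 and 20 of the 24 mesenchymal transition genes were higher in both.

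**Figure D4:**
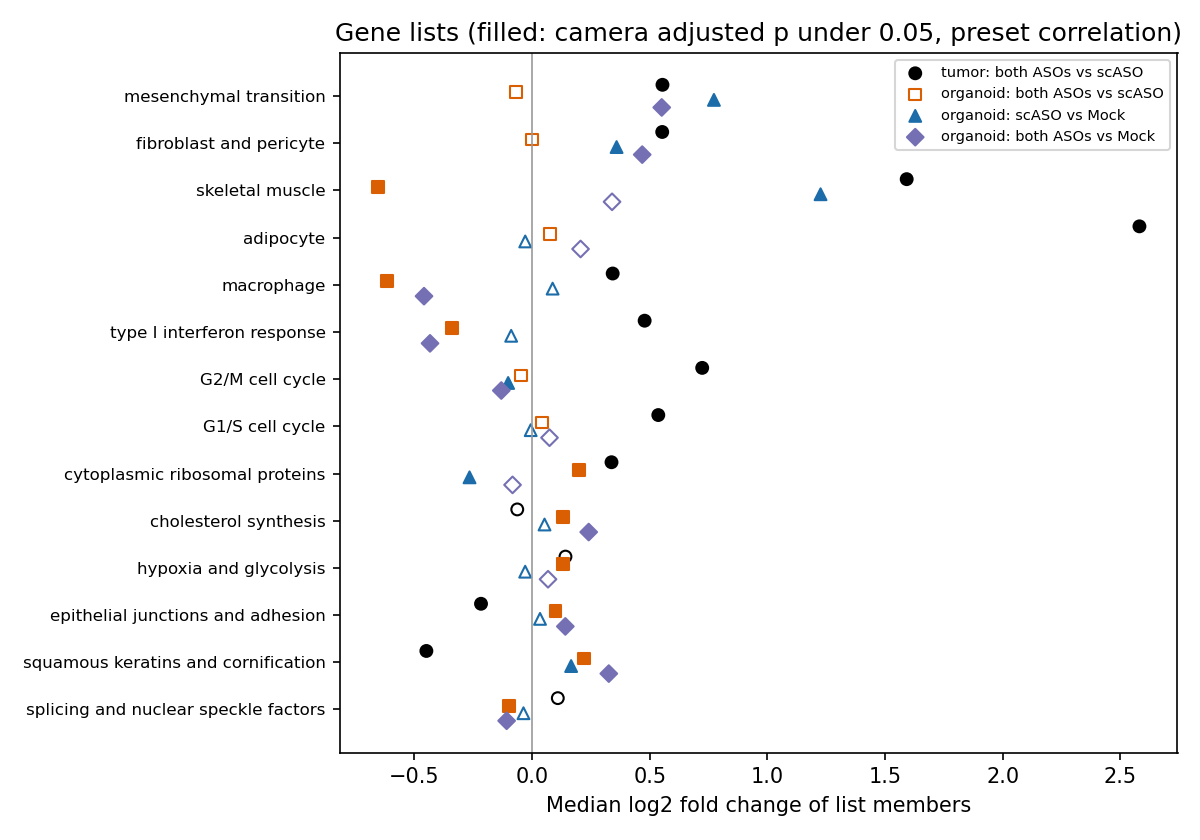
Median log2 fold change of 14 gene lists (horizontal axis) in tumors over both ASOs against scASO and, in the blocked organoid fit without the 2 libraries that went against their labels, over both ASOs against scASO, scASO against Mock and both ASOs against Mock. Filled symbols passed camera with the preset correlation. The mesenchymal transition medians were 0.55 in tumors and, in organoids, 0.77 for scASO against Mock and -0.07 for ASOs against scASO.

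The response to Malat1 ASOs was compared between tumors and organoids. As labelled, edgeR called 0 of 18695 genes for the difference of the responses (831 at an unadjusted p under 0.05, and 1 called without ASO2 tumor 4). DESeq2 called 2 and limma voom 280. The G2/M cell cycle list differed in 28 of 28 genes (median 1.08 higher in tumors, 24 called adjusted over the list alone and 0 over all genes). It had adjusted p = 1.8e-32, and adjusted p = 0.213 with an estimated correlation. The G1/S cell cycle list differed in 25 of 25 (median 0.845, adjusted p = 1.78e-17, and adjusted p = 0.328 with an estimated correlation). With the replicate block and without the library labelled ASO2 replicate 1 and the library labelled scASO replicate 2, the medians were 0.61 for G2/M cell cycle (adjusted p = 1.63e-11, and adjusted p = 0.388 with an estimated correlation) and 0.29 for G1/S cell cycle (adjusted p = 5.88e-05, and adjusted p = 0.533 with an estimated correlation). With the replicate block within each system edgeR called 57 genes, 9 higher and 48 lower in the tumor response. Without the same 2 libraries it called 15, 3 higher and 12 lower. This block also pairs tumors by number, although tumors with the same number did not resemble each other. ASO2 tumor 4, the only tumor with number 4, then has no weight in the contrast. The blocked calls rest on that pairing. Of those 15, Prr9 (-7.70 ± 0.97), Soga3 (-2.69 ± 0.37), the membrane protease St14 (-0.83 ± 0.12), the chitinase Chit1 (-1.81 ± 0.27) and the tetraspanin Cd82 (-0.79 ± 0.12) had lower estimates in the tumor response than in the organoid response. Rims2 (2.49 ± 0.40), Slc47a1 (2.73 ± 0.46) and Fbln1 (1.73 ± 0.30) went the other way. Single libraries set the size of the Prr9 value in the fit without the block: it was at -8.15 with all libraries, -1.78 without scASO tumor 1, -2.85 without ASO1 organoid 4, -3.18 without ASO2 organoid 4 and -21.56 without scASO organoid 4. In ASO1 organoids Prr9 ran from 0.0248 to 750 CPM. Fbln1 was there at 1.47 with all libraries and 0.76 without scASO organoid 4. Over 16302 genes tested in both systems, 0 were called in both, and the fold changes correlated at -0.02 (Pearson) and -0.02 (Spearman) across genes.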

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

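The tests of exchanged labels, of failed treatment, of added fibroblasts, of a response to any of the oligonucleotides, of adjacent tissue in 1 tumor and of a response to either ASO were chosen only after the result was seen. The test of gene length and GC content and the counts over other splits of the libraries were written before.

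Some libraries stood far from the others of their group, in 16 of 195 tests of groups of 4; chance flags about 1 in 20 groups. The library labelled ASO2 replicate 1 of the organoids had 1343 CPM of Malat1, and Mock organoid 4 had 1661 CPM of Neat1. In ASO2 tumor 1 the 10 most abundant genes took 8.91% of the gene reads, and ASO2 organoid 4 had 65146030 gene reads. As mean log2 CPM, ASO2 tumor 1 stood apart in B and plasma cell genes (1.303), ASO2 tumor 2 in hypoxia and glycolysis (6.71) and ASO2 tumor 4 in mesenchymal transition (3.27). Among ASO1 organoids, number 2 stood apart in nerve and Schwann cell genes (3.21), number 3 in splicing and nuclear speckle factors (7.145) and number 1 in the unfolded protein and integrated stress response (6.46). ASO2 organoid 3 stood apart in MMTV-PyMT malignancy and invasion genes (6.36). The same held for scASO organoid 3 in the neighbours of Malat1 (4.79) and in mesenchymal transition (4.17), and for scASO organoid 4 in neutrophil genes (2.55). In Mock it held for number 4 in immediate early genes (6.08) and for number 3 in splicing and nuclear speckle factors (7.24).

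A pair of organoid libraries had Malat1 levels that went against their labels: the library labelled ASO2 replicate 1 (1343 CPM) and the library labelled scASO replicate 2 (106 CPM). If the treatment had failed or taken hold by mistake in correctly numbered cultures, each would resemble its own replicate number most. The correlation with its own number instead lay below that with another (differences of -0.266 and -0.191), while the other 6 libraries tested lay above (0.249 to 1.298). Both of the 2 correlated best with the number of the other, with Malat1 left out of the correlation, which is what an exchange of the 2 libraries or of their files needs. An exchange therefore stays open as a candidate explanation, found and tested on the same libraries, and no biological explanation was tested.

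Mesenchymal transition genes were higher with scASO than with Mock in organoids, as labelled in each of the 4 replicate numbers. Added fibroblasts would bring their abundant collagens. Col1a1, Col1a2, Col3a1 and Dcn gained 45.3 ± 39.7 CPM (SD, 3 pairs, without number 2). Fn1, Tnc and Vim gained 1128 ± 502 CPM, so the former gain was 4.02% of the latter. This argues against fibroblasts as the main source of the gain in Fn1, Tnc and Vim. The collagen set still rose in all 3 pairs, and the fibroblast and pericyte list was called higher with the block. A smaller share of added fibroblasts therefore stays open, as do other cells that lack these collagens. A trend with gene length or GC content is argued against as well. Removing it left 96.9% of the list's median (0.43 before and 0.42 after, with interquartile ranges of 0.63 and 0.58). A response to any of the 3 oligonucleotides, which may shift these genes whatever the sequence, also stays open. With no Mock library shared, the median for both Malat1 ASOs was 94.8%, 122.5% and 201.1% of that for scASO. The labels give Mock the same 6 days with renewal on day 3. How Mock cultures were handled otherwise is not stated there, so handling is an untested alternative.

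Adipocyte and skeletal muscle genes were both higher over both ASOs in tumors, while with ASO1 alone muscle genes were lower in 16 of 22 (median -0.80, adjusted p = 0.122). For muscle over both ASOs, the values are those that adjacent tissue in ASO2 tumor 1 would give. Without it the median became -11.3% of its value (from 1.59 to -0.18), and such tissue is a candidate explanation. With ASO2 alone and without this tumor, 20 of 21 muscle genes were still higher (median 0.85, camera adjusted p = 0.0032). This tumor is therefore not the whole source of the rise with ASO2. For adipocyte genes this tumor is argued against as the whole cause, since without it 85.9% of the median was left (2.22 from 2.58, higher in 17 of 18 genes, adjusted p = 4.79e-08). A response to Malat1 knockdown by either ASO cannot be told apart from differences between few tumors, because the ASO1 median was 17.7% of the ASO2 median (0.69 and 3.87) and 3 tumors with ASO1 and 3 with scASO leave its spread wide: the ASO1 list was not called (adjusted p = 0.185), and its median was 0.13 without ASO1 tumor 3. As mean log2 CPM, adipocyte genes were at 5.18, 1.25, 4.24 and 3.44 in ASO2 tumors 1 to 4. They were at 0.35, 0.32 and 1.72 in ASO1 tumors and at 0.48, 0.70 and 0.07 in scASO tumors. Fat next to the tumor in other ASO2 libraries was not tested.

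The response to ASOs differed between tumors and organoids as labelled in 16 lists, each past camera with the preset correlation in a test of the difference itself and not with an estimated correlation. As tumor minus organoid medians, G2/M cell cycle was at 1.08 and G1/S cell cycle at 0.845 (0.61 and 0.29 with the replicate block and without the 2 libraries that went against their labels), replication-dependent histones at 0.77, p53 targets at 0.11, mitochondrially encoded genes at 0.56 and splicing and nuclear speckle factors at 0.11. Adipocyte genes were at 2.43, skeletal muscle at 1.90, fibroblast and pericyte at 0.67, macrophage at 0.81 and basal and myoepithelial genes at 0.46. Below 0 were squamous keratins and cornification (-1.80), epithelial junctions and adhesion (-0.26), hypoxia and glycolysis (-0.24), the unfolded protein and integrated stress response (-0.17) and cholesterol synthesis (-0.16). Single tumors carried part of the tumor side. In tumors the muscle median was -0.18 without ASO2 tumor 1 and the macrophage median -0.02 without ASO1 tumor 3. The squamous median there was 0.11 without scASO tumor 1.

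Reads with several alignments, which enter no comparison, were at 30.2 ± 6.49% of gene reads in the 7 ASO tumors (25.6 to 44.0%), all 7 above the highest scASO tumor (25.1%). The 3 scASO tumors were at 24.65 ± 0.505% (exact two-sided permutation test of the means, p = 0.167).

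Other splits of the same libraries were fitted in the same way. For scASO against Mock with the replicate block, 1 of 35 splits called as many genes as the real one (128 genes, the highest other 3), but the numbers pair these libraries. Only 8 of the splits keep 1 library of each number on each side, too few for a share under 0.05, and among them the highest other called 1. For both ASOs against Mock with the block, 2 of 100 splits reached the real 738 (the highest other 945), and the split with 945 points to a structure of the libraries. Among the 22 of these that take 1 control per number, 1 reached it, the real one, and the highest other called 110. This is the smallest share that 22 splits allow, so chance is less likely but not excluded. For ASO1 against scASO in tumors the 10 splits are too few for a share under 0.05, with 1 gene in the real split and 0 as the highest other. The real split called 0 genes in the remaining comparisons, so that every split reaches it by construction and these counts cannot test chance. In tumors these were 35 of 35 for ASO2 against scASO (highest other 8) and for ASO1 against ASO2 (66), and 100 of 100 for both ASOs (74). In organoids they were 35 of 35 for ASO1 against scASO (1760), ASO2 against scASO (0), ASO1 against ASO2 (0) and scASO against Mock without the block (1060), and 100 of 100 for both ASOs (1190). For the difference of the responses 100 of 100 reached it (33). The splits with 1760 and 1060 genes set numbers 3 and 4 against 1 and 2, a structure of the organoid libraries by replicate number. With the block, ASO1 against scASO called 0.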

How the results depend on the processing

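The fits without the 2 organoid libraries that went against their labels, the block with Mock as control, DESeq2 with the block and the block for the lists of scASO against Mock were chosen after seeing the data. The other alternatives were fixed before the data were examined. Over all results and alternatives, 2284 values kept their direction and their side of the threshold, 77 lost a call, 138 gained one, 47 reversed and 39 counts moved by more than 1.5 times. Of these, 1427, 34, 30, 32 and 8 came from leaving out 1 library. For both ASOs against scASO in tumors, and Malat1 with it, the fit of only the compared groups is the same fit and gave no separate value. Malat1 was lower in tumors in every alternative and over both ASOs in organoids too. Between the normalizations (TMM and DESeq2 size factors in edgeR) no count of called genes moved. At the depth, spread and number of libraries of the tumors, 26 of 100 simulated 2-fold changes were recovered for both ASOs and 17 of 100 for ASO1, so single genes with such changes were mostly not detectable. Depth was not varied apart from the others. Where a value below differs from that of the report, the cause was not tested.

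DESeq2 called 130 genes for ASO1 in tumors (1 by edgeR), 44 for ASO2, 18 for both, 164 for ASO1 against ASO2, 1 by both ASOs and 2 for the difference of the responses (0 by edgeR in these 5). With no filter edgeR called 3 for ASO1 and 4 for ASO1 against ASO2 in tumors, and with only the compared groups 0 for ASO1. Limma voom called 3974 genes for ASO2 and 1029 for both ASOs in organoids and 280 for the difference of the responses, and turned Irf7 in tumors (-0.22), Malat1 with ASO2 in organoids (0.38), Cd14 over both ASOs (-0.14) and Postn for scASO against Mock (0.24). With an estimated correlation 0 lists were called in tumors, in organoids and for scASO against Mock, down from 17, 7 and 13.

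In tumors, same-numbered libraries correlated at -0.215 to 0.166 in their deviations from the group means, with 2 of 9 pairs over 0.1, so they share only a number. With the replicate block ASO1 called 0 genes there (without Slc47a1), and the type I interferon response list was at adjusted p = 0.0738. In blocked fits ASO2 tumor 4, the only tumor with number 4, has no weight in the comparisons. In organoids the block gave 128 genes for scASO against Mock, or 588 with DESeq2, and within each system it gave 57 for the difference of the responses. Tumor lists called with the block numbered 18, of which 14 were higher and 4 lower, against 17 without it (13 higher and 4 lower). As the interferon list lost its call, other tumor lists gained one with the block. They are not named here. Other organoid calls that changed with the block are given in the report.

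With the block and Mock as control, 407 genes were called for ASO1, 312 for ASO2 and 738 for both. The 738 became 148 without number 2 and 257 without Mock 2. With all libraries Organoid Malat1 was at -2.47 and 20 lists were called, against 16 with Mock and no block. These settings turned the cytoplasmic ribosomal proteins (adjusted p = 0.364 without and 0.401 with the block), skeletal muscle (3.84e-05 and 0.00951) and type I interferon response lists (0.00174 and 0.00109). With the block and without the 2 libraries, counts were 1 for ASO1, 3 for ASO2, 4 for both, 1 by both ASOs, 308 for scASO against Mock, 15 for the difference of the responses and 11 lists, with Malat1 at -2.67. There Cd14 (-0.058), Luc7l3 (-0.23), the G1/S cell cycle list (adjusted p = 0.269) and the type I interferon response list (1.49e-12) turned direction. Luc7l3 was at -0.12 without the 2 libraries and no block.

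Leaving out 1 library at a time gave 0 to 1 genes for ASO1 in tumors (0 without ASO1 tumor 2 or any scASO tumor), 0 to 1 for ASO2, 0 to 1 for ASO1 against ASO2 and 0 to 1 for the difference of the responses. Organoid lists numbered 6 to 11 (11 without scASO 3). Results that turned direction in such fits ran from -0.086 to 4.43 for Acta1, -4.54 to 0.11 for Krt16, -0.53 to 0.07 for Sbsn and -0.031 to 0.53 for Irf7 in tumors. In organoids they ran from -0.20 to 0.29 for Cd14 and -0.066 to 0.11 for Luc7l3, and for scASO against Mock from -1.46 to 0.27 for Atp6v1c2 and -0.47 to 0.16 for Postn. As adjusted p, organoid lists that turned ran from 1.95e-05 to 0.757 for skeletal muscle, 5.1e-05 to 0.97 for squamous keratins and cornification and 4.2e-10 to 0.938 for the type I interferon response. For scASO against Mock they ran from 0.000807 to 0.959 for milk protein and secretory differentiation and from 0.000292 to 0.821 for macrophage genes.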

Other observations

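The test of a response to any oligonucleotide, quoted below, the fits without the 2 organoid libraries that went against their labels and the lists of ASO1 against ASO2 with 1 tumor left out were chosen only after the result was seen.

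Other gene groups also differed between ASO and scASO tumors. Replication-dependent histones were higher in 16 of 17 genes over both ASOs (median 0.79, Hist1h1d 1.27 ± 0.48, SE, and the most abundant, Hist1h1c, 0.52 ± 0.44). For the list replication-dependent histones camera gave adjusted p = 4.92e-05, and adjusted p = 0.405 with an estimated correlation. Histone reads are shared among near-identical copies, and polyadenylated RNA holds few of them. All 15 mitochondrially encoded genes were higher (median 0.65, mt-Co1 0.55 ± 0.46, adjusted p = 0.000583, and adjusted p = 0.529 with an estimated correlation). Mitochondrial reads took 7.25% of the gene reads in ASO2 tumor 1 and 1.58 to 2.41% in the other 9 tumors. Without that tumor the median was 0.28, again higher in 15 of 15 (adjusted p = 0.0098). In the p53 targets list 19 of 24 were higher (median 0.21), with Ccng1 at 0.43 ± 0.17, Gtse1 at 0.66 ± 0.27 and Sesn1 at 0.59 ± 0.32. Its adjusted p was 0.0193, and adjusted p = 0.508 with an estimated correlation. This call ended without ASO1 tumor 3 (adjusted p = 0.186, median 0.048) or scASO tumor 1 (adjusted p = 0.187, median 0.14), and without ASO2 tumor 1 the median was 0.12. The nerve and Schwann cell list was lower in 8 of 13 genes (median -0.12, adjusted p = 0.00609, adjusted p = 0.508 with an estimated correlation, and adjusted p = 0.127 with ranks). Its median was -0.41 without ASO1 tumor 3, -0.26 without scASO tumor 3, -0.22 without ASO2 tumor 2, -0.21 without ASO2 tumor 1 and -0.19 without scASO tumor 1. In it the adhesion molecule L1cam was at -1.10 ± 0.23, the 1 member called adjusted over the list alone (0 without scASO tumor 1), Sox10 at -0.56 ± 0.19 and Mbp at -0.51 ± 0.18. Sox10 was also among the abundant genes of these tumors, at a mean log2 CPM of 8.98. None of the genes of this paragraph was called over all genes.

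The ASOs differed from each other in tumors in further lists. Of the basal and myoepithelial list 19 of 20 genes were higher with ASO1 than with ASO2 (median 1.25, adjusted p = 5.38e-05, and adjusted p = 0.61 with an estimated correlation). Without ASO1 tumor 3 the median was 0.51 and the list was not called (adjusted p = 0.159). Against scASO the smooth muscle actins Actg2 and Acta2 were at 4.39 ± 1.27 and 1.76 ± 0.85 with ASO1. Of the immediate early genes list 21 of 26 were lower with ASO1 than with ASO2 (median -0.55, adjusted p = 3.49e-06, and adjusted p = 0.269 with an estimated correlation). Against scASO, Zfp36 was at -0.58 ± 0.16, Jund at -0.85 ± 0.23, Jun at -0.79 ± 0.28 and Dusp1 at -0.71 ± 0.25 with ASO1. T and NK cell genes were lower with ASO1 than with ASO2 in 19 of 22 (median -0.72, adjusted p = 5.38e-05, and adjusted p = 0.61 with an estimated correlation). Without ASO1 tumor 3 their median was -1.34. None of these genes was called over all genes.

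In organoids with the replicate block and without the 2 libraries that went against their labels, macrophage genes separated the ASOs. Of these 21 of 22 were higher with ASO1 than with ASO2 (median 0.49), 7 called adjusted over the list alone and 0 over all genes. For the macrophage list adjusted p = 1.45e-16, and adjusted p = 0.269 with an estimated correlation. Against Mock, splicing and nuclear speckle factors were lower over both ASOs in 23 of 31 genes (median -0.11). The list had adjusted p = 0.000218, adjusted p = 0.0381 with an estimated correlation, and adjusted p = 0.000132 by fry. Called were 9 over all genes and 10 adjusted over the list alone, among them the kinase Clk1 (-0.26 ± 0.05), Luc7l (-0.32 ± 0.07), Srsf11 (-0.24 ± 0.05) and Pnisr (-0.30 ± 0.06). The most abundant member, the speckle scaffold Srrm2, was at 0.05 ± 0.10. With scASO against Mock the same list was not called (19 of 31 lower, median -0.04, adjusted p = 0.246). The type I interferon response list was lower with ASOs than with Mock in 29 of 30 genes (median -0.43, Oas2 -0.93 ± 0.18, Rtp4 -0.51 ± 0.13, Ifi44 -0.87 ± 0.22, Isg15 -0.58 ± 0.16). Called were 6 over all genes and 20 adjusted over the list alone, with adjusted p = 3.92e-09, and adjusted p = 0.43 with an estimated correlation.

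Single genes stood out with scASO against Mock in this fit. The hair root keratin Krt25 rose by 3.05 ± 0.23 on the log2 scale, the hyaluronan receptor Layn by 1.03 ± 0.11, the semaphorin receptor Plxnd1 by 0.99 ± 0.10 and the receptor kinase Axl by 0.86 ± 0.10. Thrsp, a regulator of lipid synthesis, fell by 0.86 ± 0.12. Their adjusted p were 0.00137, 0.00137, 0.00137, 0.00339 and 0.00511 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

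The choice of control set some results. Titin (Ttn) fell by 1.93 ± 0.26 for ASOs against scASO, and scASO lay above Mock by 1.98 ± 0.30 in the same fit. For Myh8 the values were -4.78 ± 0.66 and 4.54 ± 0.71. With no Mock library shared, the mesenchymal transition median for both Malat1 ASOs was at least 94.8% of that for scASO. Part of what separates organoids given a Malat1 ASO from Mock may thus not depend on Malat1, a hypothesis found on these libraries.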
